A study of Homo sapiens with 9 samples.

How the data were processed

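RNA of ES-2 cells, a human ovarian cancer line, was sequenced in 9 libraries from 3 groups of 3: cells carrying an empty vector, cells overexpressing OTUB2 and cells overexpressing SNX29P2. Per the labels' protocols, cells grew in RPMI-1640 with serum, total RNA was extracted with TRIzol, and libraries followed a standard Illumina preparation. Each library was placed in its group by the genotype given in the labels. The labels do not say that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

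The authors deposited 1 table of RPKM values (reads per kilobase of gene length and 1000000 reads) for 32997 genes, with exon positions and gene lengths, per the file headers. Positions refer to GRCh38, per the submitters' processing notes. The aligner, the counting program, its handling of strand and of reads matching several places, and the annotation release are not given in the sources used here. Multiplied by gene length, the values of each library summed to 1000000. Below 1000 reads, 100% of the values were whole multiples of the value of 1 read, within a tolerance of 0.05 reads. Whole reads were therefore recovered for every gene, and they gave 38504854 to 48551215 reads in genes per library. Of the values below 1000 reads, 58.1 to 60.4% were even in each library, so reads need not be independent molecules. Intervals from reads cover counting error only and treat reads as independent. 25 gene names had been turned into dates by spreadsheet software and were left unnamed. For annotation, GENCODE release 29 held 22740 of the names, 21142 of them at the same start and end.

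Genes with at least 0.5 RPKM in at least 3 libraries were tested, 16533 in all. Values were log2(RPKM + 0.1), so fold changes are on that scale and understate the change of low genes. 1 limma model (version 3.58.1, R 4.3.3) with a trended variance was fitted to all 9 libraries with group as the only term. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The 3 comparisons were OTUB2 against vector, SNX29P2 against vector, and OTUB2 against SNX29P2, the last being the test of a difference between the overexpression effects. The design written before the data were examined named a count test for a table of counts and this limma test for RPKM. The table held RPKM, so the limma test was used. Tables and plots were made with python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

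Gene lists (39 lists, 871 entries) were fixed before the data were examined. They cover hypoxia, carbon and lipid metabolism, mitochondria, stress and signalling pathways, antigen presentation, proliferation, ribosome and proteasome, matrix, ubiquitin and sorting nexin families, markers of other cell types and signs of RNA quality. 35 entries were matched through an older symbol and 17 were not matched. Each list was tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over lists within a comparison. Calls were also counted after adjustment over the list alone. Agreement between the effects of OTUB2 and SNX29P2 was measured as the correlation and covariance of fold changes across genes. Because both effects use the same vector libraries, these were set beside 100 simulations of unchanged groups.

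The rule for named genes was also fixed beforehand. It always takes OTUB2, SNX29P2, SNX29, CA9, HIF1A and VHL. Against the vector it takes the 10 highest and 10 lowest fold changes among called genes with a gene symbol, a mean of at least 1 RPKM in 1 group and no overlap between the libraries of the groups. For OTUB2 against SNX29P2 it takes 5 and 5. From each list it takes up to 3 called members, or up to 2 with the smallest p where no member was called.

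Alternatives were pseudocounts of 1 and 0.01, no filter, a filter of 1 RPKM in 6 libraries, median-of-ratios scaling, quantile normalization, a robust variance fit, only the compared groups, a replicate block, each library left out, and a minimum log2 fold change of 1. For the agreement of fold changes, genes with a mean of at least 5 RPKM were also taken alone. Added after seeing the data were limma voom on the recovered reads, fits without the transgenes or without the libraries numbered 2, lists without CA9, and a contrast of both overexpression groups together with the vector. The programs were tested on simulated data with 200 seeded genes and with the HIF targets lowered. Each simulated gene had the median spread of genes at its level, and libraries were drawn independently. The simulated comparison called 149 genes, more than any real comparison, which eases the adjusted threshold. The recovery below may therefore overstate the power of the real comparisons. In the simulated OTUB2 comparison with 16532 genes, 54.5% of 66 genes changed by 1.5-fold were called, 67.7% of 65 changed by 2-fold and 84.4% of 64 changed by 4-fold, with 4 unchanged genes called.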

Results

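Transcriptomes of ES-2 cells were compared between an empty vector, OTUB2 overexpression and SNX29P2 overexpression, with 3 libraries in each group. OTUB2 encodes a deubiquitinating enzyme, and SNX29P2 is annotated as a transcribed pseudogene of the sorting nexin gene SNX29. The title of the series connects OTUB2 with mitochondrial metabolism and with the carbonic anhydrase CA9, so the question was how OTUB2 and SNX29P2 alter CA9, hypoxia-responsive and metabolic genes. Reads in genes, in units of 1000000, came to 42.7, 38.5 and 41.3 in the vector libraries, 42.4, 48.6 and 39.9 with OTUB2, and 45.8, 39.9 and 47.2 with SNX29P2. Group means in these units were 40.8 ± 2.13, 43.6 ± 4.43 and 44.3 ± 3.86 (SD, n = 3). Libraries of 1 group correlated at 0.971 to 0.981 across genes on the log2 scale, and differed by more than counting noise, with a chi-square of 10.3 to 32.8 per gene. At this depth and spread, the median standard error of a log2 fold change was 0.126, and its 95% interval reached 0.28 to either side, a factor of 1.22.

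Each transgene was high in its own group and low elsewhere. OTUB2 (chromosome 14, 94026329 to 94048930, GRCh38) was at 37.6, 42.6 and 38.4 RPKM in the OTUB2 libraries, against 1.31, 1.16 and 1.04 with the vector and 1.05, 1.58 and 1.08 with SNX29P2. SNX29P2 (chromosome 16, 29350746 to 29370272) was at 41.0, 55.1 and 47.6 RPKM in its own libraries. It had 13378 reads over that group, 8 over the vector group and 4 over the OTUB2 group, a ratio to the vector of 1541 (95% counting interval 782 to 3570). The parent gene SNX29 stayed low, at 1.61 ± 0.207 RPKM with the vector, 1.51 ± 0.0779 with OTUB2 and 1.67 ± 0.187 with SNX29P2 (SD, n = 3). Reads of the constructs and of the chromosomal genes were not separated here.

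**Figure D1:**
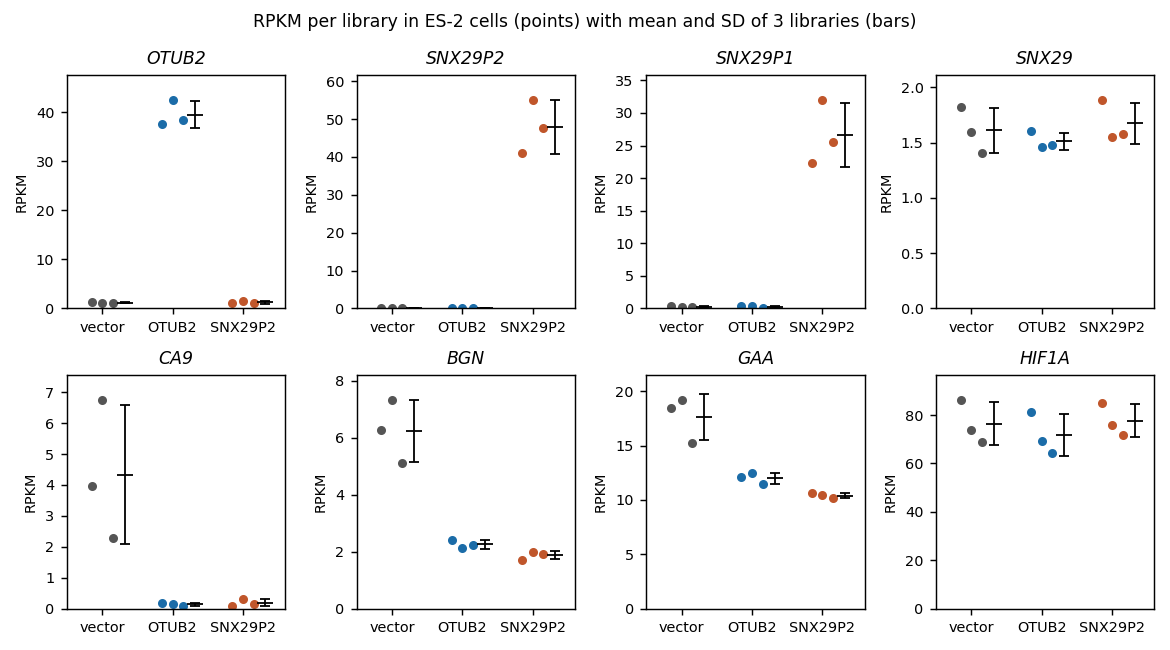
RPKM (y axis) of 8 genes in each library (points) by group (x axis), with the mean and SD of 3 libraries beside the points. CA9 lay at 2.29 to 6.75 RPKM in the vector libraries and at 0.0900 to 0.330 in the 6 overexpression libraries, and HIF1A overlapped between the groups.

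With OTUB2 overexpression, CA9 and BGN fell. CA9, the membrane carbonic anhydrase that is a classical target of hypoxia-inducible factor (HIF), dropped from 3.96, 6.75 and 2.29 RPKM with the vector to 0.198, 0.148 and 0.0900 RPKM, that is from 282, 434 and 158 reads to 14, 12 and 6. Its log2 fold change was -4.07 (SE 0.421; limma, Benjamini-Hochberg adjusted p = 0.0173), a 16.8-fold reduction on the fitted scale. BGN, which encodes the matrix proteoglycan biglycan, went from 6.24 ± 1.10 to 2.26 ± 0.147 RPKM (SD, n = 3), with a log2 fold change of -1.41 (SE 0.132; limma, Benjamini-Hochberg adjusted p = 0.0109). CA9 lies at 35673856 to 35681159 on chromosome 9 and BGN at 153494939 to 153509554 on the X chromosome. OTUB2 itself was the other called gene, 31.3-fold higher (log2 fold change 4.97, SE 0.151; limma, Benjamini-Hochberg adjusted p = 6.48e-07).

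These 3 genes, 1 higher and 2 lower, were the only calls among 16533 genes in this fit. An unadjusted p under 0.05 was found for 1112 genes, where chance gives 827. With the replicate number as a block it was found for 1934, and 4 genes were called. The libraries of the groups did not overlap in 10.8% of genes, where chance gives 10%. HIF1A, the oxygen-regulated subunit of HIF, was at 76.4 ± 8.86 RPKM with the vector and 71.7 ± 8.60 with OTUB2 (SD, n = 3), a log2 fold change of -0.09 (adjusted p = 0.928). VHL, which targets that subunit for degradation, had a log2 fold change of 0.04 (adjusted p = 0.983), and SNX29 -0.08 (adjusted p = 0.961). The call of CA9 was lost without vector replicate 1 (adjusted p = 0.128), vector replicate 2 (0.117) or OTUB2 replicate 1, 2 or 3 (0.0693, 0.105 and 0.0879), and that of BGN without vector replicate 1 (0.0756) or OTUB2 replicate 1, 2 or 3 (0.0566, 0.0976 and 0.0697). The log2 fold changes in these fits were -3.69 to -4.22 for CA9 and -1.37 to -1.46 for BGN. The count was 1 in the fits without vector replicate 1 or any of the OTUB2 libraries, 2 without vector replicate 2 and 8 without vector replicate 3.

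Among the metabolic lists, genes of mitochondrial respiration encoded in the nucleus tended higher with OTUB2, and lipid synthesis, glycolysis and mitochondrially encoded genes tended lower. Of 37 measured genes of respiratory complex I, 30 were higher (median log2 fold change 0.08; limma camera, Benjamini-Hochberg adjusted p = 0.00218; adjusted p = 0.468 with an estimated correlation), with no member called, NDUFV2 at 0.20 and NDUFC2 at 0.15. Complexes III to V (28 of 35 higher, median 0.05, adjusted p = 0.0165; adjusted p = 0.562 with an estimated correlation) were also called upward. So were the tricarboxylic acid cycle (20 of 25 higher, median 0.07, adjusted p = 0.0210; adjusted p = 0.468 with an estimated correlation) and the mitochondrial ribosome (27 of 36 higher, median 0.07, adjusted p = 0.0112; adjusted p = 0.468 with an estimated correlation). In the opposite direction, 11 of 13 mitochondrially encoded genes were lower (median -0.16, adjusted p = 0.000706; adjusted p = 0.468 with an estimated correlation), and 3 passed when adjusted over the list alone, MT-CYB at -0.23, MT-CO2 at -0.24 and MT-CO3 at -0.25. The mitochondrial chromosome took 4.45, 4.64 and 4.79% of reads with OTUB2, against 5.23, 5.10 and 4.97% with the vector. With SNX29P2 it took 4.60, 4.96 and 4.79%, also below each vector library, so the lower share is not particular to OTUB2. Cholesterol synthesis genes were lower in 19 of 23 cases (median -0.24, adjusted p = 0.000253; adjusted p = 0.468 with an estimated correlation). Fatty acid synthesis was lower in 10 of 15 (median -0.12, adjusted p = 0.0325; adjusted p = 0.468 with an estimated correlation; SCD -0.74) and glycolysis in 13 of 19 (median -0.04, adjusted p = 0.0352; adjusted p = 0.468 with an estimated correlation; ALDOC -1.18). ALDOC passed when adjusted over the list alone and not over all genes (adjusted p = 0.481).

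Each of these calls was also lost in some fits with 1 library left out, and the median of fatty acid synthesis turned to 0.01 without vector replicate 1. Without vector replicate 1 the adjusted p was 0.173 for complex I, 0.567 for complexes III to V, 0.0694 for the tricarboxylic acid cycle, 0.289 for the mitochondrial ribosome and for glycolysis, 0.468 for cholesterol synthesis and 0.226 for fatty acid synthesis. Without vector replicate 2 it was 0.0517 for complex I, 0.0544 for complexes III to V, 0.102 for the tricarboxylic acid cycle and 0.0660 for the mitochondrial ribosome. Without vector replicate 3 it was 0.0555 for mitochondrially encoded genes and for fatty acid synthesis and 0.132 for glycolysis. Without OTUB2 replicate 1 it was 0.192 for complexes III to V, 0.0692 for fatty acid synthesis and 0.0974 for glycolysis, without replicate 2 it was 0.161 for fatty acid synthesis and 0.107 for glycolysis, and without replicate 3 it was 0.0917 for the tricarboxylic acid cycle, 0.0662 for complexes III to V and 0.171 for the mitochondrial ribosome. Medians that moved while the call stayed were -0.09 for glycolysis without vector replicate 2, 0.12 for complex I and -0.41 for cholesterol synthesis without vector replicate 3, and -0.08 for mitochondrially encoded genes without OTUB2 replicate 1. Where a call was lost without vector replicate 1, the median was 0.03 for complex I, for complexes III to V and for the mitochondrial ribosome, -0.06 for cholesterol synthesis and -0.02 for glycolysis. It was 0.05 for the tricarboxylic acid cycle and 0.04 for the mitochondrial ribosome without vector replicate 2, 0.04 for the latter without OTUB2 replicate 3, -0.02 for glycolysis without OTUB2 replicate 1 and -0.07 for fatty acid synthesis without OTUB2 replicate 2.

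HIF target genes as a list lay lower with OTUB2, in 22 of 27 members, with a median log2 fold change of -0.15 and a mean of -0.31 (limma camera, Benjamini-Hochberg adjusted p = 0.000551; adjusted p = 0.468 with an estimated correlation). CA9 was the only member called over all genes tested and over the list alone. Without vector replicate 1 the median was -0.04 and the adjusted p 0.0865. Carbonic anhydrases and pH regulators, which include CA9, had 5 of 8 members lower (median -0.09, mean -0.55, adjusted p = 0.0367; adjusted p = 0.468 with an estimated correlation), and that call was lost without vector replicate 2 (0.551) or OTUB2 replicates 1 or 3 (0.0974 and 0.0917), with a median of -0.00 without vector replicate 2 and -0.14 without vector replicate 3. With CA9 left out of the lists, the carbonic anhydrase list was not called (median -0.07, adjusted p = 0.431), and the HIF targets were (median -0.13, adjusted p = 0.00466).

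**Figure D2:**
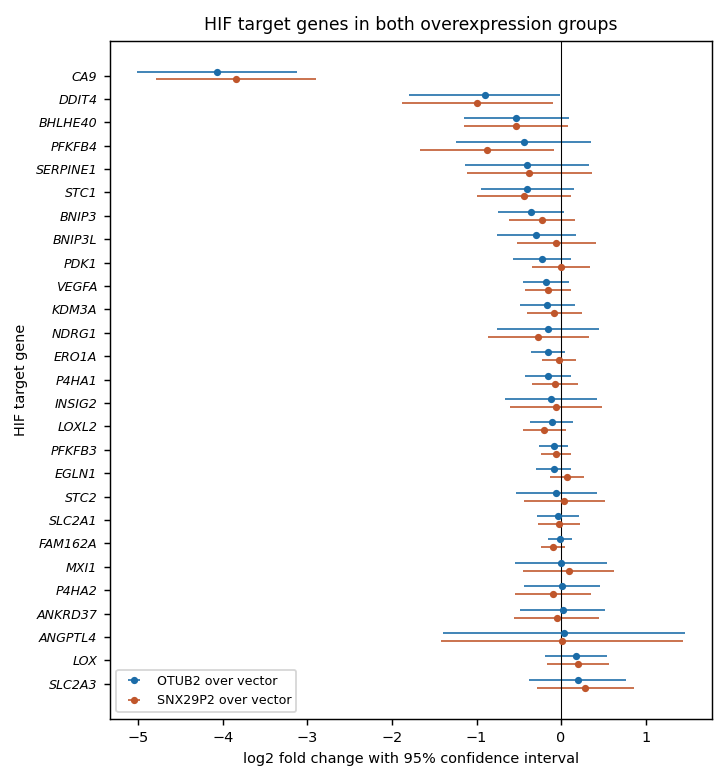
Log2 fold change against the vector (x axis, points) with its 95% confidence interval (lines) for the 27 measured HIF target genes (y axis), with OTUB2 and with SNX29P2 overexpression. CA9 stands at -4.07 and -3.85, and the list has medians of -0.15 and -0.07.

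Proliferation, proteasome and heat shock lists lay higher with OTUB2, and inflammatory and antigen presentation lists lower. All 30 measured genes of the G2/M phase and mitosis were higher (median 0.30; limma camera, Benjamini-Hochberg adjusted p = 1.21e-09; adjusted p = 0.468 with an estimated correlation), with none called, MKI67 at 0.33 and BIRC5 at 0.36. Vector replicate 2 had the lowest level of this list, and without it the median was 0.09 (adjusted p = 0.0138), while without vector replicate 3 it was 0.45. The proteasome list was higher in 30 of 31 members (median 0.11, adjusted p = 6.82e-07; adjusted p = 0.468 with an estimated correlation; median 0.06 without vector replicate 2 and 0.18 without vector replicate 3). DNA replication was higher in 25 of 32 (median 0.06, adjusted p = 0.0317; adjusted p = 0.468 with an estimated correlation) and heat shock in 14 of 15 (median 0.20, adjusted p = 0.000275; adjusted p = 0.468 with an estimated correlation). Among heat shock genes DNAJB4, a co-chaperone, was at 0.66 and passed when adjusted over the list alone. Lower were targets of the inflammatory factor NF-kB (18 of 20, median -0.19, adjusted p = 0.000319; adjusted p = 0.468 with an estimated correlation; median -0.12 without vector replicate 2), with the prostaglandin synthase PTGS2 at -1.01. Also lower was antigen presentation by major histocompatibility complex class I (10 of 12, median -0.14, adjusted p = 0.00405; adjusted p = 0.468 with an estimated correlation), with PSMB8 at -0.27 passing over the list alone. The cytosolic ribosome (41 of 49, median -0.06, adjusted p = 0.000475; adjusted p = 0.562 with an estimated correlation; RPL3 -0.23) and YAP and TAZ targets (17 of 23, median -0.08, adjusted p = 0.0127; adjusted p = 0.468 with an estimated correlation; IGFBP3 -0.54) were lower too. So were immediate early genes (15 of 20, median -0.09, adjusted p = 0.0233; adjusted p = 0.468 with an estimated correlation; EGR1 -0.83) and 3 markers of stromal cells (3 of 3, median -0.28, adjusted p = 0.0278; adjusted p = 0.468 with an estimated correlation; COL1A1 -0.28).

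The G2/M, proteasome and NF-kB lists were the 3 of the 20 called lists that passed without every single library in turn. Heat shock was lost without vector replicate 1 (adjusted p = 0.0865). Its mean level, centred over the libraries, was 0.40, -0.03 and -0.04 in the OTUB2 libraries and -0.49, -0.08 and -0.19 with the vector, so OTUB2 replicate 1 stood highest. The same library was highest for histone genes (0.49, against -0.12 and -0.01 in OTUB2 replicates 2 and 3), a list kept as a sign of RNA quality. YAP and TAZ targets (0.233) and class I antigen presentation (0.0517) were lost without vector replicate 2. DNA replication was lost without vector replicate 1 or 3 (0.0865 each) and OTUB2 replicate 2 or 3 (0.0646 and 0.0662), and the cytosolic ribosome without vector replicate 3 (0.207) or OTUB2 replicate 2 (0.152). Immediate early genes were lost without vector replicates 2 or 3 (0.233 and 0.0555) or OTUB2 replicate 3 (0.120), and stromal markers without vector replicates 1, 2 or 3 (0.0830, 0.0573 and 0.0649) or OTUB2 replicates 1 or 2 (0.150 and 0.0556). Medians that moved were, for YAP and TAZ targets, -0.13 without vector replicate 3 and -0.11 without OTUB2 replicate 2, and for the cytosolic ribosome -0.09 without vector replicate 1 and -0.03 without vector replicate 3 or OTUB2 replicate 2. They were 0.02 for DNA replication without vector replicate 3, -0.03 for immediate early genes without vector replicate 2, and for stromal markers -0.18 without vector replicate 1 and -0.16 without OTUB2 replicate 1.

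Over the 39 lists, camera at the preset correlation called 20 with OTUB2, 8 upward and 12 downward, but 9 without vector replicate 1 and 12 without vector replicate 2. With an estimated correlation it called 0, with 3 lists at an unadjusted p under 0.05. The fry test called 3, namely the tricarboxylic acid cycle, fatty acid oxidation and DNA replication (adjusted p = 0.0430 each), and had 6 lists at an unadjusted p under 0.05. The 19 lists not called by camera had an adjusted p of 0.0576 to 0.943. They were the HIF regulatory machinery, mitochondrial biogenesis, fatty acid oxidation, serine and one-carbon metabolism, the ATF4 and unfolded protein responses, NRF2 targets, p53 targets, the interferon response, MYC and nucleolar genes, the ovarian tumour deubiquitinase family, matrix and mesenchymal genes, angiogenic growth factors, clear cell ovarian markers, sorting nexins, epithelial, leukocyte and endothelial markers, histones and small noncoding RNAs. In these lists NQO1 (0.39) and TXNRD1 (0.25) among NRF2 targets, COL6A2 (-0.58) among matrix genes and SPP1 (0.78) among clear cell markers passed only when adjusted over the list alone. MMP3, a matrix metalloprotease, had a log2 fold change of 2.15, with 40.4 ± 37.5 RPKM against 6.88 ± 0.495 with the vector (SD, n = 3; adjusted p = 0.606).

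With SNX29P2 overexpression, CA9 and BGN again lay below the vector, and GAA fell as well. CA9 was at 0.104, 0.330 and 0.152 RPKM (8, 22 and 12 reads), with a log2 fold change of -3.85 (SE 0.421; limma, Benjamini-Hochberg adjusted p = 0.0168). BGN was at 1.88 ± 0.136 RPKM (SD, n = 3), with a log2 fold change of -1.67 (SE 0.132; limma, Benjamini-Hochberg adjusted p = 0.00124). GAA (chromosome 17, 80101556 to 80119879), the lysosomal enzyme that breaks down glycogen, went from 17.6 ± 2.12 to 10.4 ± 0.221 RPKM, with a log2 fold change of -0.75 (SE 0.0897; limma, Benjamini-Hochberg adjusted p = 0.0317). The higher genes were SNX29P2 (log2 fold change 8.55, SE 0.231; limma, Benjamini-Hochberg adjusted p = 2.18e-07) and a pair of genes sharing its sequence.

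That pair consisted of SNX29P1, another pseudogene of SNX29 on chromosome 16 at 21376648 to 21386064 (log2 fold change 6.20, SE 0.350; limma, Benjamini-Hochberg adjusted p = 7.39e-05), and RP11-231C14.7, at 29291220 to 29372110 on the same strand as SNX29P2 and overlapping it (7.49, adjusted p = 2.72e-07). GENCODE 29 gives the entry at the place of RP11-231C14.7 the name SNX29P2 too, so the calls count this locus 2 times. RP11-231C14.7 falls outside the naming rule and was chosen after its values were seen. In the SNX29P2 libraries its reads numbered 3976, 4652 and 4750, equal to those of SNX29P2, and SNX29P1 had 25.9, 27.7 and 25.6% as many reads as SNX29P2. Of the 50-base words in their transcripts, 65.6% of those of SNX29P1 and 32.8% of those of RP11-231C14.7 occur in SNX29P2, against 1.24% for SNX29, so the levels of both are uncertain.

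The 6 calls, 3 higher and 3 lower, stood beside 1358 genes at an unadjusted p under 0.05, where chance gives 827. With the replicate number as a block, 9 calls stood beside 2272 such genes. The libraries did not overlap in 11.7% of genes, where chance gives 10%. HIF1A was at 77.6 ± 6.78 RPKM (SD, n = 3; log2 fold change 0.02, adjusted p = 0.976), and VHL (0.11, adjusted p = 0.840), SNX29 (0.05, adjusted p = 0.950) and OTUB2 (0.06, adjusted p = 0.951) were not called. BGN, SNX29P2, SNX29P1 and RP11-231C14.7 were called without every single library in turn. CA9 was lost without vector replicate 1 (adjusted p = 0.145), vector replicate 2 (0.112), SNX29P2 replicate 1 (0.0771) or SNX29P2 replicate 3 (0.123), with log2 fold changes of -3.47 to -3.85. GAA was lost without vector replicate 1 (0.145) or 2 (0.134), SNX29P2 replicate 1, 2 or 3 (0.141, 0.180 and 0.226) or OTUB2 replicate 1, 2 or 3 (0.0823, 0.0844 and 0.0851), with log2 fold changes of -0.68 to -0.76, and had a log2 fold change of -0.54 with OTUB2 (adjusted p = 0.355).

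Antigen presentation and ribosomal genes lay lower with SNX29P2, and G2/M genes higher. All 12 measured genes of class I antigen presentation were lower (median -0.18; limma camera, Benjamini-Hochberg adjusted p = 5.23e-06; adjusted p = 0.310 with an estimated correlation), and HLA-B at -0.98, HLA-C at -0.44, TAPBP at -0.20 and PSMB8 at -0.33 passed when adjusted over the list alone. Of 49 cytosolic ribosomal protein genes 48 were lower, by a small amount (median -0.12, adjusted p = 3.21e-13; adjusted p = 0.546 with an estimated correlation), with RPL3 at -0.23. All 30 G2/M genes were higher (median 0.28, adjusted p = 1.14e-08; adjusted p = 0.628 with an estimated correlation), with MKI67 at 0.35. Without vector replicate 2 that median was 0.08 (adjusted p = 0.0193), and without vector replicate 3 it was 0.44. NF-kB targets (17 of 20 lower, median -0.25, adjusted p = 0.000181), immediate early genes (18 of 20 lower, median -0.12, adjusted p = 0.000653) and matrix and mesenchymal genes (22 of 31 lower, median -0.10, adjusted p = 0.000653) lay lower, each with an adjusted p = 0.546 with an estimated correlation. Among these, NFKB2 was at -0.39, DUSP4 at -0.26 and the collagen gene COL6A2 at -0.70 (adjusted p = 0.244), the last passing when adjusted over the list alone. The NF-kB median was -0.12 without vector replicate 2 and -0.12 without SNX29P2 replicate 3, and the matrix median was -0.15 without SNX29P2 replicate 2. These 6 lists were called without every single library in turn.

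Of the other called lists with SNX29P2, heat shock (14 of 15 higher, median 0.23, adjusted p = 6.46e-05; adjusted p = 0.546 with an estimated correlation; DNAJB4 0.85) was lost without vector replicate 1 (0.0514), and the proteasome (29 of 31 higher, median 0.10, adjusted p = 0.000298; adjusted p = 0.711 with an estimated correlation) without vector replicate 2 (median 0.03, adjusted p = 0.337). The mean level of heat shock genes was 0.39, 0.00 and 0.04 in the SNX29P2 libraries, and replicate 1 was also highest of these for histone genes (0.30). The proteasome median was 0.16 without vector replicate 3 and 0.06 without SNX29P2 replicate 3. Cholesterol synthesis was lower in 21 of 23 genes (median -0.24, adjusted p = 6.45e-05; adjusted p = 0.667 with an estimated correlation), but its median was -0.01 without vector replicate 1 (adjusted p = 0.384) and -0.38 without vector replicate 3. HIF targets were lower in 20 of 27 genes (median -0.07, mean -0.29, adjusted p = 0.00616; adjusted p = 0.564 with an estimated correlation), and lost without vector replicate 1 (median -0.02, adjusted p = 0.497), with medians of -0.11 and -0.12 without vector replicates 2 and 3 and -0.11 without SNX29P2 replicate 3. Glycolysis was lower in 12 of 19 genes (median -0.02, adjusted p = 0.0150; adjusted p = 0.616 with an estimated correlation), and lost without vector replicates 1 or 3 (0.223 and 0.0599), with medians of -0.08 without vector replicate 2 and -0.05 without SNX29P2 replicate 1. YAP and TAZ targets (17 of 23 lower, median -0.10, adjusted p = 0.0329) and stromal markers (3 of 3 lower, median -0.30, adjusted p = 0.0497) each had an adjusted p = 0.546 with an estimated correlation. The former were lost without vector replicate 2 (0.376) or SNX29P2 replicates 1 or 3 (0.168 and 0.0507), the latter without vector replicates 1, 2 or 3 (0.162, 0.0847 and 0.0736) or SNX29P2 replicate 1 (0.424). The median of the YAP and TAZ targets was -0.07 without vector replicate 1, -0.06 without vector replicate 2 and -0.06 without SNX29P2 replicate 1, and that of the stromal markers -0.14 without vector replicate 1.

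Camera at the preset correlation thus called 13 lists with SNX29P2, 3 upward and 10 downward, and 8 without vector replicate 1. The other 26 had an adjusted p of 0.103 to 0.846. With an estimated correlation it called 0, with 3 lists at an unadjusted p under 0.05. The fry test also called 0, with 5 lists at an unadjusted p under 0.05. The respiratory chain lists were not called against the vector, with medians of 0.02 for complex I (adjusted p = 0.705) and 0.02 for complexes III to V (adjusted p = 0.846).

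Between OTUB2 and SNX29P2 overexpression, the direct comparison called the transgenes and the genes sharing sequence with SNX29P2. OTUB2 was higher with OTUB2 by 4.91 on the log2 scale (SE 0.151; limma, Benjamini-Hochberg adjusted p = 2.41e-07), and SNX29P2, RP11-231C14.7 and SNX29P1 were lower, at -8.72 (adjusted p = 1.81e-07), -7.59 (adjusted p = 2.41e-07) and -6.22 (adjusted p = 5.34e-05). CA9 differed by -0.22 (95% interval -1.16 to 0.72), BGN by 0.25 (-0.04 to 0.55) and GAA by 0.20, and none of these was called. The 4 calls stood beside 402 genes at an unadjusted p under 0.05 (778 with the replicate number as a block, which called the same 4), where chance gives 827, and the libraries did not overlap in 8.35% of genes, where chance gives 10%.

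Nuclear respiratory chain and ribosomal genes lay slightly higher with OTUB2 than with SNX29P2. Of 37 complex I genes 30 were higher (median 0.07; limma camera, Benjamini-Hochberg adjusted p = 0.00267; adjusted p = 0.760 with an estimated correlation), with NDUFA8 at 0.19. Of 35 genes of complexes III to V 29 were higher (median 0.05, adjusted p = 0.0183; adjusted p = 0.784 with an estimated correlation), with ATP5I at 0.42. Fatty acid oxidation was higher in 12 of 16 genes (median 0.09, adjusted p = 0.0319; adjusted p = 0.499 with an estimated correlation), with ECI1 at 0.51. The cytosolic ribosome was higher in 48 of 49 genes (median 0.07, adjusted p = 1.77e-06; adjusted p = 0.771 with an estimated correlation), with RPLP1 at 0.22 and a median of 0.11 without SNX29P2 replicate 1. The calls of complex I and of complexes III to V were lost without OTUB2 replicate 1 (adjusted p = 0.0546 and 0.191), OTUB2 replicate 3 (0.0562 and 0.117) or SNX29P2 replicate 2 (0.0912 and 0.334). That of fatty acid oxidation was lost without OTUB2 replicate 2 or 3 (0.0632 and 0.117) or SNX29P2 replicate 1 or 2 (0.0558 and 0.153). For complex I the median was 0.05 without OTUB2 replicate 1 and 0.04 without SNX29P2 replicate 2, and for complexes III to V 0.08 without SNX29P2 replicate 1 and 0.02 without SNX29P2 replicate 2. Camera at the preset correlation called 4 lists, all upward, but 7 without OTUB2 replicate 1, 1 without SNX29P2 replicate 2, 8 without SNX29P2 replicate 3 and 9 with the replicate number as a block, these 4 included. The other 35 had an adjusted p of 0.0523 to 0.988. With an estimated correlation it called 0, with 2 lists at an unadjusted p under 0.05, and fry called fatty acid oxidation (adjusted p = 0.0286).

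Across genes, the fold changes of OTUB2 and SNX29P2 against the vector correlated at 0.552, with the same sign in 74.0% of genes. Both share the 3 vector libraries, and 100 simulations of unchanged groups with a common spread gave a mean correlation of 0.499 (highest 0.544) and the same sign in 66.7%. The covariance was 0.0406, against a simulated mean of 0.0332 and a highest value of 0.0379, a difference of 0.00736. With the own spread of each group, a simulation run after the first had been seen, the simulated mean was 0.0392 and the highest 0.0459, which the observed covariance did not exceed. Without vector replicate 2 the covariance was 0.0524, within the simulated range with a common spread (highest 0.0544). Without vector replicate 1 it was 0.0596 (highest 0.0544) and without vector replicate 3 0.0670 (highest 0.0550), both above that range. Among genes with a mean of at least 5 RPKM the covariance was 0.0156 (highest simulated 0.0102), with the same sign in 75.9% (simulated mean 66.7%). The correlation there was 0.489, not above the simulated mean of 0.496. This set still held the transgenes, whose changes the simulations lack, so its correlation cannot show a lack of excess. CA9 and BGN were called lower in both comparisons. Independent lists would share 0.000363 genes, but these comparisons share the vector libraries, so that value is no yardstick. In 20 simulated draws with a common spread, at most 1 gene was shared. Draws with the own spread of each group were not run for this count. No gene was called higher in both. The 3 vector libraries are too few to be divided between the comparisons, so part of any excess may come from the shared controls.

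**Figure D3:**
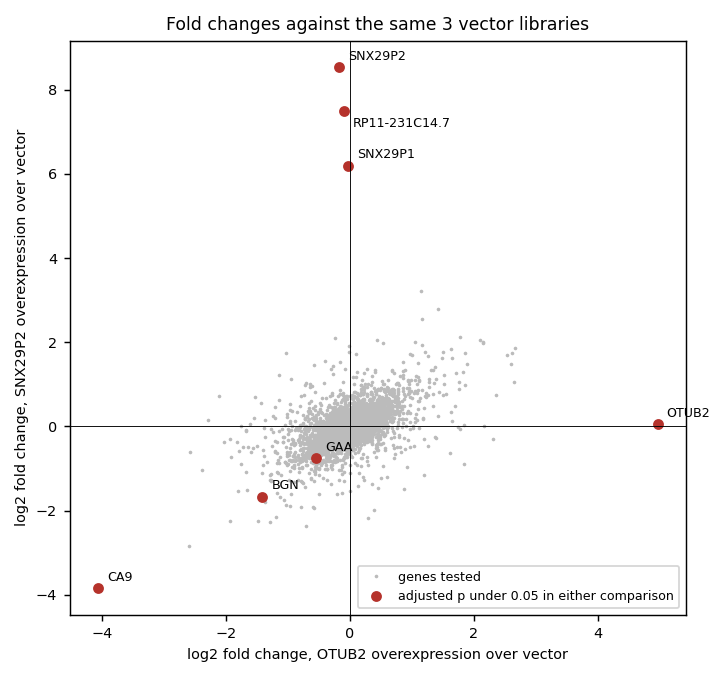
Log2 fold change of each tested gene with OTUB2 (x axis) and with SNX29P2 (y axis) over the same 3 vector libraries, with genes called in either comparison in red. CA9 and BGN lie low on both axes, OTUB2 stands at 4.97 on the x axis and SNX29P2 at 8.55 on the y axis.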

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

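The tests of a single vector library, of a state of the vector cells and of the shared vector libraries were chosen after the results were seen; the predictions for the others were written before those tests were run. The direct comparison called 4 genes, namely the transgenes and the entries sharing sequence with SNX29P2. For the transgenes the constructs fix this outcome in advance. Without these 4 genes, 0 others were called. The log2 difference was 4.91 for OTUB2, -8.72 for SNX29P2, -7.59 for RP11-231C14.7 and -6.22 for SNX29P1. Also called were 4 lists, with medians of 0.0716 for respiratory complex I, 0.0477 for complexes III to V, 0.0861 for fatty acid oxidation and 0.0669 for the cytosolic ribosome. These list calls were lost with an estimated correlation, and 5 of the 10 splits of the 6 libraries called as many lists. A difference between the effects beyond the transgenes and the entries sharing their sequence is thus not shown.

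The first pattern is the low CA9 and BGN in both overexpression groups. For denser or more hypoxic vector dishes, the prediction was that other HIF targets lie lower too, by a median of at least 0.3 on the log2 scale. That size was chosen, not measured. The run that showed this pattern also gave list medians with CA9 of -0.15 and -0.07, so the outcome could be foreseen. The 26 targets other than CA9 had a median of -0.13 with OTUB2 (95% bootstrap interval over genes -0.19 to -0.06) and -0.07 with SNX29P2 (-0.15 to -0.02), short of the predicted size. The intervals treat genes as independent and hold no spread between the vector libraries, so they cannot bound such a state. Values that go with a smaller shift are 21 and 19 of the 26 targets lower and camera calls without CA9 (adjusted p = 0.00466 and 0.0370). Such a state therefore stays open. A single vector library is argued against, since at least 90.1% of each log2 fold change remained without any 1 of them. A state of the shared vector cells that acts on these genes alone cannot be told apart from a like effect of both transgenes, because the direct difference of -0.22 for CA9 (-1.16 to 0.72) and 0.25 for BGN (from -0.04) includes 0 and both predict that.

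The second pattern is the rise of SNX29P1 and RP11-231C14.7 with SNX29P2. For SNX29P1, reads shared between near-identical copies are a candidate explanation, since 65.6% of its 50-base words occur in SNX29P2. For RP11-231C14.7 the share is 32.8%, and this entry overlaps SNX29P2 on the same strand. The ratio of reads to those of SNX29P2 varied between the 3 libraries by a factor of 1.08 for SNX29P1 and 1 for RP11-231C14.7. Equal reads are what counting 1 set of reads for both overlapping entries would give. RP11-231C14.7 has exons that SNX29P2 lacks, and its equal reads in all 3 libraries argue against an induction that adds reads there. For SNX29P1, reads of its own and reads of SNX29P2 were not separated.

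The third pattern is the correlation of the fold changes of OTUB2 and SNX29P2. Without the transgenes and the genes sharing their sequence, the covariance was 0.0407. It lay above the highest of 100 simulations with a common spread (0.0376), run first, and below the highest with the own spread of each group (0.0452), run second. The vector libraries varied more, with a mean variance of 0.117 against 0.0908 and 0.0911, so the share of the covariance due to the shared vector libraries cannot be told apart from a shared response. The simulations drew all libraries independently, so deviations shared by OTUB2 and SNX29P2 libraries of 1 number are not covered by them.

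Other splits of the libraries were counted for each comparison, and 10 splits of 6 libraries are too few for a share under 0.05. For OTUB2 against the vector the real split called 3 genes and the highest other 0 (1 split of 10 reached the real count), with 20 lists against 13 (1 of 10). For SNX29P2 it called 6 genes against 1 (1 of 10) and 13 lists against 14 (2 of 10). The direct comparison gave 4 genes against 1 (1 of 10) and 4 lists against 10 (5 of 10). These splits kept the transgenes and the genes sharing their sequence, so the constructs gave the real split calls in advance. Without those genes the real comparisons called 2, 2 and 0 genes, and the other splits were not rerun. The gene counts therefore do not weigh the remaining calls.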

How the results depend on the processing

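The fits with voom, without the transgenes, without the libraries numbered 2, with the block and an estimated correlation together, and with the own spread of each group were chosen after seeing the data. The transgene log2 fold changes passed in all settings where they were tested, at 4.89 to 5.04 for OTUB2 and 8.37 to 8.74 for SNX29P2 with 1 library left out, and at 4.81 to 5.09 and -8.82 to -8.61 in the direct comparison. No call changed direction. Besides the counts below, 243 fold changes of named genes and 117 list results were followed over settings, and they lost a call in 191 cases and gained one in 44; other genes that gained a call enter only the counts.

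With OTUB2 against the vector, 3 genes became 7 with no filter, 1 with only the compared groups, 1 without the libraries numbered 2, and 1 to 8 with 1 library left out. CA9 had an adjusted p of 0.0137 to 0.396 over settings (limma, Benjamini-Hochberg adjusted), 0.0897 with voom. BGN had 0.00343 to 0.396. With SNX29P2, 6 genes became 1 with the filter of 1 RPKM in 6 libraries, which leaves CA9 and SNX29P2 untested, and 10 with voom. They became 2 without the transgenes and the genes sharing their sequence, 3 without the libraries numbered 2, and 4 to 8 with 1 library left out. CA9 had an adjusted p of 0.0126 to 0.285, BGN 0.000391 to 0.0912 and GAA 0.00430 to 0.722. In the direct comparison 4 genes became 1 with the stricter filter, 4 to 5 with 1 library left out, and 0 without the transgenes (limma, 399 genes at an unadjusted p under 0.05). Called lists numbered 0, 0 and 0 with an estimated correlation, with or without the block. Without the libraries numbered 2 they numbered 12 for OTUB2 and 2 in the direct comparison, and with 1 library left out 9 to 21, 8 to 15 and 1 to 8. The correlation of fold changes was 0.552 with the own spread of each group, 0.600 with that spread and no transgenes, and 0.535 without the libraries numbered 2, each within its simulations. It was 0.614 to 0.669 with 1 vector library left out, and within the simulations without replicate 2. The causes of these changes were not tested.

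The design written beforehand had no replicate block, because no label says that a number marks a shared day or culture. A threshold of 0.1 for pairing was also not passed by all 9 same-numbered pairs. The deviations of these pairs correlated at -0.018 to 0.270. The 3 pairs of OTUB2 with SNX29P2 libraries were above 0.1 (0.153 to 0.270). Pairs of different numbers reached at most 0.0502. Each of the 9 libraries had its highest correlation with a library of its own number, 7 of them in both other groups. Structure by replicate number was thus present although not every pair passed the threshold. The main fit has group as its only term, so its p-values count this structure as spread between libraries. The values given for chance, 827 genes and 10% of genes, assume libraries without such structure. With a replicate block, 4, 9 and 4 genes were called, including the 3, 6 and 4 called without it, and 19, 13 and 9 lists. edgeR and DESeq2 were not run, because the table holds RPKM.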

Other observations

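All fits in this part were chosen after seeing the data. BGN and CA9 lay below the vector when the 6 libraries of both overexpression groups were compared with the 3 of the vector. With the transgenes in the fit, 6 other genes were called, namely BGN (limma, Benjamini-Hochberg adjusted p = 0.000691), CA9 (0.00373), GAA (0.0276), and PLTP, AEBP1 and RP11-37C7.1 (0.0458 each). PLTP encodes a phospholipid transfer protein and AEBP1 a protein that binds collagen. Without the transgenes and the genes sharing their sequence, BGN (log2 fold change -1.54, adjusted p = 0.00276) and CA9 (-3.96, adjusted p = 0.00933) were called. These 2 genes stood beside 1502 at an unadjusted p under 0.05. GAA (-0.64, adjusted p = 0.0645), PLTP (-0.63), AEBP1 (-0.52) and RP11-37C7.1 (-0.57, adjusted p = 0.0763 for these 3) were then not called. KISS1, which encodes a secreted peptide precursor, was at -1.59 and COL6A2 at -0.64 (adjusted p = 0.234 each). With 1 library left out 1 to 7 genes were called. CA9 was lost without vector replicate 1 (adjusted p = 0.0851) or 2 (0.0933), and 7 genes were called without vector replicate 3.

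A fit of the 6 libraries against the 3 as 2 groups called 4 genes without the transgenes. Of the 84 splits of the 9 libraries into 3 and 6, 3 gave as many, the real one included. That share is not a chance rate, because the contrast was chosen after CA9 and BGN had been seen. The libraries are also not interchangeable between replicate numbers. The highest other split, the 3 libraries numbered 2 against the others, called 181 genes, which points to a structure of the samples that sets number 2 apart. The splits by number 1 and by number 3 called 0 genes each (limma), and another split called 6. With the replicate number as a block, 11 genes were called in the real contrast. They were BGN and CA9 (adjusted p = 0.0176 each), GAA, PLTP, RP11-37C7.1, COL6A2 and FSTL3 (0.0339 each), COL6A1, JUNB and IL11 (0.0456 each), all lower, and IL24 (0.0342), higher. No label says what a number marks.

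The libraries numbered 2 were compared with the other 6 only because of that split, and 109 of the 181 genes were higher and 72 lower in them. With group kept in the model 177 genes were called, 109 higher and 68 lower. Among the genes higher in these libraries were the small GTPase gene RHOB (log2 difference 0.68, adjusted p = 0.0150), INHBA, which encodes an activin subunit (0.51, adjusted p = 0.0157), and TIMP3, an inhibitor of metalloproteases (0.71, adjusted p = 0.0197). The splicing factor gene SRSF5 (-0.56, adjusted p = 0.0173) and the snoRNA host gene SNHG3 (-0.52, adjusted p = 0.0189) were lower. Splicing factor genes went both ways, since SRSF2 (0.47, adjusted p = 0.0346) and SF1 (0.49, adjusted p = 0.0315) were higher. These genes were chosen after their values were seen, and adjusted p-values are from limma with Benjamini-Hochberg adjustment.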
